A study of Homo sapiens and Mus musculus with 17 samples.

How the data were processed

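Total RNA was sequenced from subcutaneous PC3 tumours and from livers of male nude mice injected with sNT1-LPP or sCAG-LPP, as the labels name them. The labels do not explain LPP. sCAG was read from its name as a short RNA of CAG repeats, and sNT1 was taken as the control arm. PC3 is a human prostate cancer cell line, so tumour reads were assigned to human genes and liver reads to mouse genes, in separate tables that share no features. The labels put 5 tumours and 3 livers in the sNT1 groups and 5 tumours and 4 livers in the sCAG groups. The libraries were made from DNase-treated total RNA with a total RNA kit, per the labels' protocols.

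The submitters' processing notes name TopHat, Bowtie2 and HTSeq without versions, and the builds hg38 and mm10, with no role or order given. Each library column of the deposited tables is a normalized signal: the authors divided the reads of each gene by 1 size factor per library. All values above 0 were whole multiples of the smallest value of their column within a tolerance of 0.01, so whole reads were recovered for 100% of the values in every library. The authors also deposited a log2 fold change, which is positive where the sNT1 mean exceeds the sCAG mean, together with a p-value and its false discovery rate adjustment from a Wald test. The program behind that test is not given in the sources used here. The mouse table held 1 line with no gene, which was left out, leaving 54231 genes, of which 22702 had at least 1 read. The human table held 58395 genes, of which 35628 had at least 1 read.

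The design chosen before the data were examined assumed read counts and named edgeR as the main test. Because the deposited unit is a normalized signal, the main test was limma 3.58.1 with an intensity trend on log2(value + 1), the alternative named in that design for this case. A fold change is therefore on the log2(value + 1) scale, and that of a low gene can be smaller or larger than edgeR's. Genes entered if they passed filterByExpr with a minimum count of 10 and a minimum total count of 15, applied to the recovered reads with the authors' size factors. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. All fold changes below compare sCAG with sNT1, opposite in sign to the authors' deposited column. In 5 cases a tumour and a liver code share the arm and number, which may mark the same animal, although the labels do not say so. The difference of list scores between tissues was tested with the tissues relabelled independently, and again, after the data were examined, with such libraries relabelled together. For genes, depth and list scores, the p-values measure the spread between the samples of a group. Camera at the preset correlation compares a list with other genes, the tumour and liver correlation permutes genes, and matched lists are drawn from genes. Those values do not measure the spread between samples.

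Gene lists for pathways and for markers of other cell types were fixed before the data were examined. Lists with at least 5 tested genes were tested on log2(value + 1), where the design had named log2 CPM, with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a tissue. Camera was repeated with the correlation estimated per list, and fry was run beside it. A list score is the mean log2(value + 1) of its tested genes in a library, compared between groups with an exact two-sided permutation test over all splits. These score tests were added after the data were examined. Human genes with uninterrupted CTG or CAG runs of at least 18 nt in an annotated transcript were found in the GENCODE 29 annotation, with runs of 12 and 24 nt as alternatives. Of the genes tested in the tumour, 12134 had an annotated transcript. These lists were also compared with 10000 random lists matched on mean level and transcript length. The same question in mouse liver was not analysed here, because no mouse transcript sequences were used.

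Genes were named by a rule fixed before the data were examined. In each tissue it took the 8 largest and 8 smallest fold changes among changed genes with a mean CPM of at least 1 in the higher group and no overlap between groups. It also took up to 4 members with the lowest p of each list called by camera or holding at least 2 changed genes, and a fixed set of genes in any case. Where fewer than 8 genes changed, the 10 genes with the lowest p were named as values. Clone-named, predicted and read-through genes were counted but replaced by the next named gene.

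The alternatives tried were edgeR 4.0.16 with 4 scalings of the recovered reads, DESeq2 1.42.0, limma-voom with quality weights, other filters and pseudocounts, robust and weighted fits, each replicate left out in turn, covariates, and thinning of all tumour libraries, by their size factors, to the depth of the shallowest. Calculations used R 4.3.3, Python 3.11.15 and SciPy 1.17.1.

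The methods were tested on data simulated from the real means, dispersions and depths, with each gene drawn independently. Shifts that many genes of a library share were not simulated, so false calls from them were not tested. With no gene changed, limma called 0 of 12146 tumour genes and 0 of 9465 liver genes. With 200 genes changed, 4-fold or 2-fold, limma recovered 78.1% of the 96 tested 4-fold and 26.3% of the 95 tested 2-fold changes in the tumour design. In the liver design it recovered 69.9% of 93 and 7.61% of 92. It called 2 unchanged genes in the tumour design and 6 in the liver design. Tumour libraries held 534988 to 8522298 reads and liver libraries 11681421 to 15838426 reads. In the shallowest tumour library, 1 read equals 10.4 normalized units, so a value of 0 there allows up to 31.3 units, the worth of 3 reads. These limits cover counting error only.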

Results

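Total RNA was measured in PC3 tumours and livers of mice given 6 injections of sNT1-LPP or sCAG-LPP over 2 weeks, each with 20 ug RNA. Treatment began on day 21 after the PC3 cells, a human prostate cancer line, were implanted, and RNA was taken 17 days later. The tumour groups held 5 libraries each, and the liver groups held 3 sNT1 and 4 sCAG libraries. The tumour libraries of the sCAG arm were shallower: they held 1.95 ± 1.26 M reads (SD, n = 5) against 5.90 ± 2.15 M (SD, n = 5) in the sNT1 arm, with an exact two-sided permutation p = 0.0159. RN7SL2, an RNA of the signal recognition particle with near-identical copies, took 63.1% ± 12.7 of the reads in sCAG tumours and 28.3% ± 13.9 in sNT1 tumours (SD, n = 5 each, exact permutation p = 0.0159). The nuclear long RNAs MALAT1 and NEAT1, chosen after their values were seen, took 0.263% ± 0.266 and 0.0483% ± 0.0599 of the reads in sCAG tumours and 1.13% ± 0.367 and 0.331% ± 0.125 in sNT1 tumours (SD, n = 5 each), shares that a higher RN7SL2 share also lowers. Reads on all other tumour genes came to 0.845 ± 0.808 M and 4.44 ± 2.14 M (SD, n = 5 each, exact permutation p = 0.0159). Among the sNT1 tumours, replicate 2 held 4483474 reads, replicate 3 held 6491254, replicate 4 held 6967151, replicate 8 held 3039628 and replicate 9 held 8522298. Among the sCAG tumours, replicate 1 held 3761270 reads, replicate 3 held 534988, replicate 5 held 2649854, replicate 7 held 1287493 and replicate 10 held 1532400. Liver libraries held 14.0 ± 1.29 M reads in the sCAG arm (SD, n = 4) and 13.2 ± 1.49 M in the sNT1 arm (SD, n = 3), with an exact permutation p = 0.457. Protein-coding genes took only 11.7% ± 4.09 of these in sCAG (SD, n = 4) and 15.5% ± 4.04 in sNT1 livers (SD, n = 3). The share of rRNA was 39.2% in sCAG and 35.6% in sNT1 livers, and that of mitochondrial rRNA 37.0% and 39.2%.

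**Figure D1:**
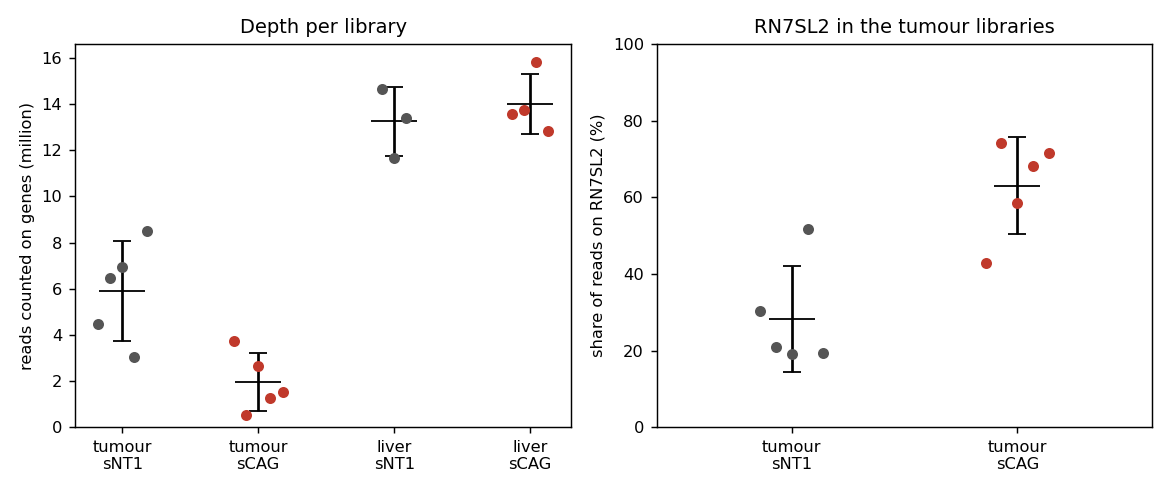
Reads assigned to genes in each library, in M reads, by tissue and treatment. The tumour sCAG libraries held 0.535 to 3.76 M reads and the tumour sNT1 libraries 3.04 to 8.52 M.

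The first comparison asked which genes of the tumour cells differed after the CAG-repeat short RNA. ADCYAP1, which encodes the neuropeptide PACAP and lies on hg38 chromosome 18 from 904943 to 912172, had the largest rise among the genes named by rule. It stood at 255 ± 377 normalized reads in sCAG tumours and 2.09 ± 3.66 in sNT1 tumours (SD, n = 5 each), a log2 fold change of 5.52 (limma adjusted p = 0.0438). The mean rested on sCAG replicate 3, the shallowest library, at 906 against 11.7 to 258 in the others, and without it the log2 fold change was 4.69 (limma adjusted p = 0.0591). The ribosomal protein gene RPS14 rose from 391 ± 146 to 1237 ± 394 normalized reads (SD, n = 5 each), and the transcription factor gene ZEB2, linked to epithelial-mesenchymal transition, rose from 45.3 ± 35.7 to 372 ± 255. The interferon-induced gene IFI44 fell from 165 ± 73.9 to 44.3 ± 15.3, and STAT2, a transcription factor of interferon signalling, fell from 838 ± 206 to 292 ± 174.2 (SD, n = 5 each). Of 12139 genes tested with limma, 577 changed, 400 of them higher in sCAG and the rest lower, with a lowest adjusted p of 0.0438, and 4335 had an unadjusted p under 0.05. The median log2 fold change of all tested genes was -0.29 with limma and between -0.12 and -0.06 with edgeR under 4 scalings. The values of 946 genes did not overlap between the arms, 7.79% of those tested against 0.794% by chance. edgeR with the authors' size factors called 1166 genes, 564 of them shared with limma, and the authors' own table called 2767. The lowest adjusted p lay near the threshold, and the count changed when 1 library was left out. With limma it was 0 without sNT1 replicate 2, 3, 4 or 9 and without sCAG replicate 3, 5, 7 or 10. It was 1034 without sNT1 replicate 8 and 4100 without sCAG replicate 1. In the fits with 0 calls the lowest limma adjusted p was 0.0531 (without sCAG replicate 5) to 0.129 (without sNT1 replicate 4). In that pair of fits 4865 and 3164 genes had an unadjusted p under 0.05. The balance also turned: without sCAG replicate 1, 1584 genes were higher and 2516 lower, and limma-voom called 1948 higher and 2289 lower.

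Other rises among the named genes included CAVIN1, which encodes a coat protein of caveolae, from 3.91 ± 3.03 to 32.3 ± 26.4 normalized reads. RNA5S9, RNU5E-1, HIST1H4I and the pseudogenes EEF1A1P15, MTND2P28 and RPS7P10 rose by log2 fold changes of 2.69 to 3.48, but they have near-identical copies that could share their reads, which was not measured, so their levels are uncertain. Processed pseudogenes were called higher in 74 of 394 cases and lower in 6, against 302 higher and 147 lower of 10810 protein-coding genes. The largest falls among the genes named by rule were those of BTN2A3P, the peptide transporter gene SLC15A2, GUSBP2, KIAA0825, NMRAL2P, MKRN5P, RN7SL648P and the chromatin remodelling gene SMARCD3, with log2 fold changes from -3.44 to -2.92. SLC15A2 stood at 2.31 ± 3.89 in sCAG and 19.3 ± 4.20 in sNT1 tumours (SD, n = 5 each). These falls rested on 8 to 36 reads in the sCAG libraries together, and 1 read was worth up to 10.4 normalized units there. edgeR with the authors' size factors gave log2 fold changes from -2.54 for GUSBP2 to -1.58 for BTN2A3P, and did not call NMRAL2P (adjusted p = 0.0601). Of the genes named in any case, none passed. The proliferation marker MKI67 stood at 141 ± 130 in sCAG and 369 ± 132 in sNT1 (limma adjusted p = 0.0588). AGO2, which carries guide RNAs in RNA interference, stood at 317 ± 76.3 and 437 ± 26.6 (limma adjusted p = 0.0799). MKI67 passed as a fall without sNT1 replicate 8 (limma adjusted p = 0.0491) and both genes did without sCAG replicate 1 (0.00411 for MKI67 and 0.0152 for AGO2). For the p53 target CDKN1A, the stress gene DDIT3 and the interferon target IFIT1, the limma adjusted p was 0.172, 0.903 and 0.817.

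Gene lists were compared next, to ask whether groups of functionally related genes moved together in the tumours. Ribosomal protein genes were higher in sCAG tumours in normalized reads: 56 of 70 rose, or 64 when adjusted over the list alone. Their median log2 fold change was 1.05 (camera adjusted p = 3.88e-38, adjusted p = 0.415 with an estimated correlation). As a share of all reads, RPS24 stood at 0.233% ± 0.0474 in sCAG and 0.280% ± 0.0287 in sNT1 tumours (SD, n = 5 each). Its log2 fold change in normalized reads was 0.71. Shares of the other ribosomal protein genes were not computed. Histone genes of replication had 6 rises among 37, 14 when adjusted over the list alone (camera adjusted p = 6.29e-09). HIST1H2AI was among them, at 64.1 ± 27.6 in sCAG against 19.1 ± 3.13 in sNT1 (SD, n = 5 each). Among 29 proteasome genes 3 rose, PSMD8, PSMB5 and PSMB6, or 12 when adjusted over the list alone (camera adjusted p = 3.51e-08). RNA polymerase II had 1 rise among 11, POLR2C, and NRF2 targets, which respond to oxidative stress, had 1 among 14, the ferritin gene FTL; each had 2 when adjusted over the list alone and a camera adjusted p of 0.00556. These 4 lists also had an adjusted p = 0.415 with an estimated correlation, so no list was called that way, and fry called ribosomal proteins alone (adjusted p = 0.0264). All 5 medians were above 0 with edgeR under the authors' size factors and TMM. The ribosomal protein score was 1.02 higher in sCAG, and 5 of 5 sCAG tumours lay above the sNT1 mean but only 4 above every sNT1 tumour (exact permutation p = 0.0159, adjusted 0.0794 over 20 lists). The score of sNT1 replicate 8, the shallowest of its arm with an RN7SL2 share of 51.7%, was 8.69, and that of sCAG replicate 1, the deepest of its arm with a share of 43.0%, was 8.61. The RNA interference machinery score was -0.50 by the same comparison, with 5 of 5 sCAG tumours below the sNT1 mean (exact permutation p = 0.0159, adjusted 0.0794), and 0 of its 13 genes passed, though 6 did when adjusted over the list alone, 1 higher and 5 lower; camera did not call it (adjusted p = 0.233, adjusted p = 0.618 with an estimated correlation).

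Interferon-stimulated genes had 3 falls among 28, IFI44, STAT2 and DDX58, and 4 when adjusted over the list alone, with a camera adjusted p of 0.292. The median log2 fold change of the list was -0.2945, against -0.2937 for all tested genes. Camera called this list lower without the 3 libraries of fewest reads (adjusted p = 4.89e-05) and with the size factor as a covariate (adjusted p = 3.11e-15). Hypoxia genes had 2 rises among 22, the glycolytic genes LDHA and ENO1, and epithelial-mesenchymal transition genes had 2 among 16, ZEB2 and VIM; camera gave 0.292 for both, and called both higher in the same pair of settings. The hypoxia median was -0.10 with limma and 0.13 with edgeR and TMM. Cell cycle genes of G2/M had a median of -0.69, with 20 of 25 below 0 and 0 passing (camera adjusted p = 0.292). That median was -0.24 with edgeR and TMM and -0.29 with the authors' size factors, and with the size factor as a covariate it was 0.44 and the list was called higher (adjusted p = 0.0303). Spliceosome and p53 target lists had 1 rise each (camera adjusted p = 0.248 and 0.667), and apoptosis regulators had 0 changed genes, or 8 when adjusted over the list alone, 4 in each direction. Leaving out sCAG replicate 3 added the spliceosome to the called lists (adjusted p = 0.0368). Of the marker lists of other cell types, fibroblasts had 6 tested genes and a median of -0.06 (camera adjusted p = 0.735), endothelial cells had 3 tested genes, all below 0 with a median of -0.89 and 1 passing when adjusted over the list alone, and keratinocytes had 2, both below 0 with a median of -0.79. Adipocyte and hepatocyte lists had 1 tested gene each, and macrophages, neutrophils, lymphocytes, erythroid cells and skeletal muscle had 0. All these marker lists hold human genes, so they do not measure cells of the mouse host.

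**Figure D2:**
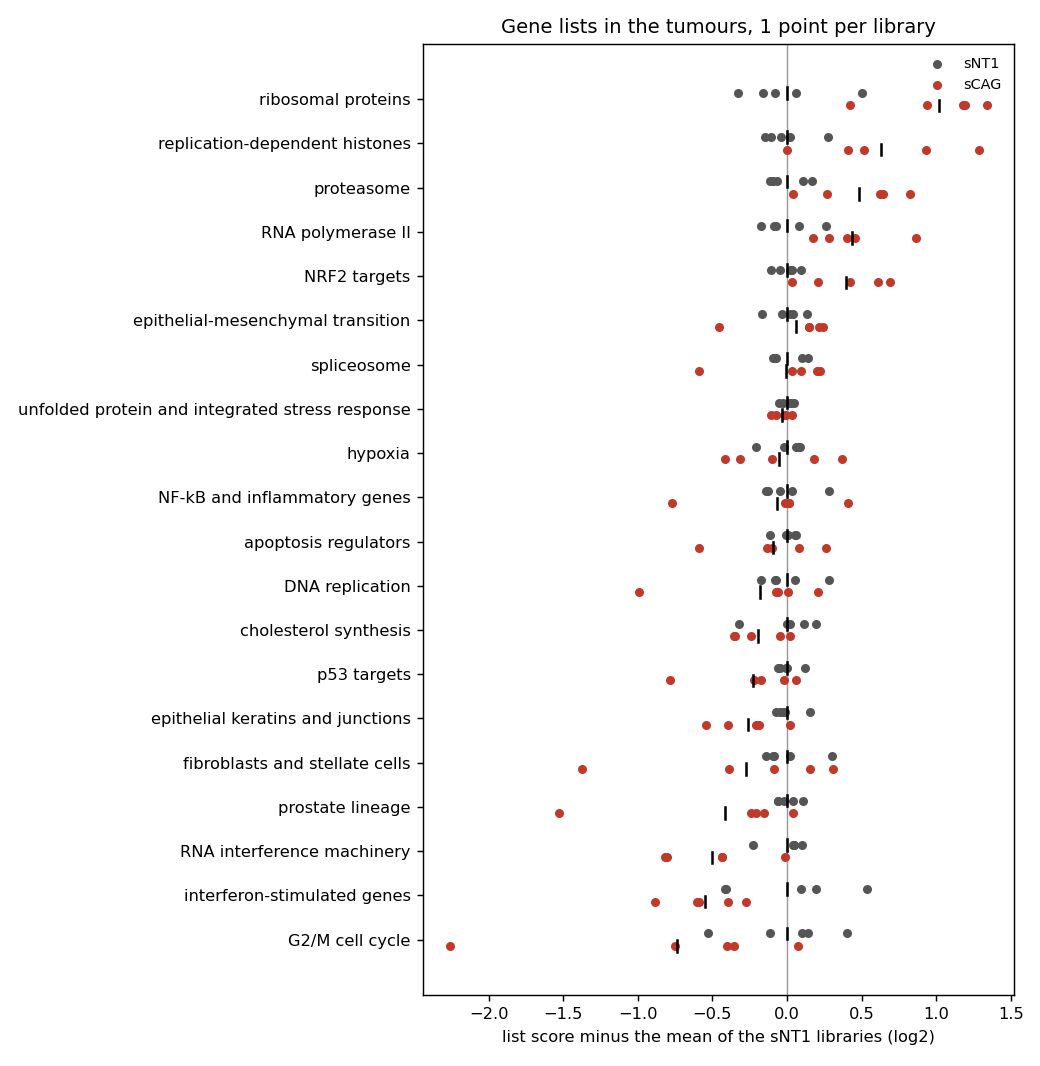
Score of each gene list in each tumour library, as the difference in log2 from the mean of the sNT1 libraries, with the mean of each group as a line. All 5 sCAG tumours lie above the sNT1 mean for ribosomal proteins.

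A further comparison asked whether transcripts with CUG repeats, which pair with a CAG-repeat strand, were lower in sCAG tumours. The 81 tested genes with CTG runs of at least 18 nt had a median log2 fold change of -0.31, against -0.29 for the others (camera p = 0.322, p = 0.604 with an estimated correlation). The median lay at percentile 73.9 among 10000 matched lists. Of these 81 genes, 1 was called higher and 1 lower. The 513 tested genes with CTG runs of at least 12 nt had a median of -0.41 (camera p = 0.142, p = 0.552 with an estimated correlation) at percentile 11.3 among matched lists. The difference of -0.02 turned above 0 without sNT1 replicate 2 (0.0247), 4 (0.000378) or 9 (0.00329). The 133 genes with CAG runs of the same length had a median of -0.52 (camera p = 0.0435, p = 0.441 with an estimated correlation) at percentile 6.53 among matched lists. For CAG runs of at least 12 nt, 562 genes had a median of -0.50 (camera p = 0.00770, p = 0.397 with an estimated correlation) at percentile 0.05, and for 24 nt, 57 genes had -0.58 (camera p = 0.0225, p = 0.356 with an estimated correlation) at percentile 10.2.

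Genes that differed between the arms were then sought in the mouse liver, where limma called no gene. The fatty acid hydroxylase gene Cyp4a14, on mm10 chromosome 4 from 115486200 to 115496142, had the lowest p and stood at 10.5 ± 10.8 normalized reads in sCAG livers (SD, n = 4) and 154 ± 119 in sNT1 livers (SD, n = 3). The glycolytic gene Pklr stood at 166.4 ± 66.2 and 455.5 ± 218, the fatty acid elongase gene Elovl6 at 37.2 ± 22.1 and 108 ± 45.7, and the plasma protein gene Mug1 at 15581 ± 3046 and 7350 ± 1983, in that order. limma called 0 of 9518 genes, with 313 at an unadjusted p under 0.05 and a lowest adjusted p of 1.00. edgeR called 0, with 358 at an unadjusted p under 0.05, limma-voom called 0, with 383, and DESeq2 called 1, Cyp4a14, as lower. The authors' Wald test also called 0, but its lowest adjusted p was 0.0504, just above the threshold. It had 637 genes at an unadjusted p under 0.05, counted over all genes with a deposited p and not over the 9518. The values of 439 genes did not overlap between the arms, 4.61% against 5.71% by chance. The other genes of lowest p were Serpina4-ps1, Slc17a8, Cyp2b9, Tkfc, Dusp1, Acss3, Ttc39c and Ces1d, with log2 fold changes from -4.03 to 2.12. Albumin, Alb, stood at 12301 ± 4782 in sCAG and 17930 ± 4604 in sNT1 livers, and the acute phase gene Saa1 at 6658 ± 3403 and 4365 ± 2152. Mki67, Cdkn1a, Ago2, Ifit1 and Ddit3 had log2 fold changes between -0.50 and 0.06.

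Of 30 lists tested in the liver, camera called 6, all lower in sCAG. Lipogenesis genes, which make fatty acids, had a median log2 fold change of -0.65 (camera adjusted p = 1.87e-09, adjusted p = 0.211 with an estimated correlation), and 3 of 17 passed when adjusted over the list alone. The lipogenesis score of 4 of 4 sCAG livers lay below every sNT1 liver (exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted 0.643 over 30 lists). Ribosomal protein genes had a median of -0.46 (camera adjusted p = 1.90e-16, adjusted p = 0.633 with an estimated correlation), with 0 of 68 genes passing. Drug-metabolising enzymes, such as Cyp2c54 and Cyp2c37, had a median of -0.37 (camera adjusted p = 0.000172, adjusted p = 0.211 with an estimated correlation). Targets of the fatty acid sensor PPAR-alpha, such as Cyp4a10 and Cd36, had a median of -0.20 (camera adjusted p = 0.000745, adjusted p = 0.514 with an estimated correlation). Cholesterol synthesis genes, such as Hmgcs1 and Sqle, had a median of -0.40 (camera adjusted p = 0.0149), and NRF2 targets, such as Hmox1 and Ftl1, had -0.26 (camera adjusted p = 0.0247), both with an adjusted p = 0.856 with an estimated correlation. The last pair lost their calls without sNT1 replicate 3 (0.0563 for cholesterol synthesis and 0.0902 for NRF2 targets), sNT1 replicate 4 (0.848 and 0.207) or sCAG replicate 4 (0.851 and 0.578). Interferon-stimulated genes were called higher without sNT1 replicate 4 (adjusted p = 1.34e-05) and lower without sNT1 replicate 2 (adjusted p = 6.19e-05). Markers of macrophages, endothelial cells, fibroblasts and cholangiocytes were not called, although macrophage markers were called lower without sNT1 replicate 3 (adjusted p = 0.0229).

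**Figure D3:**
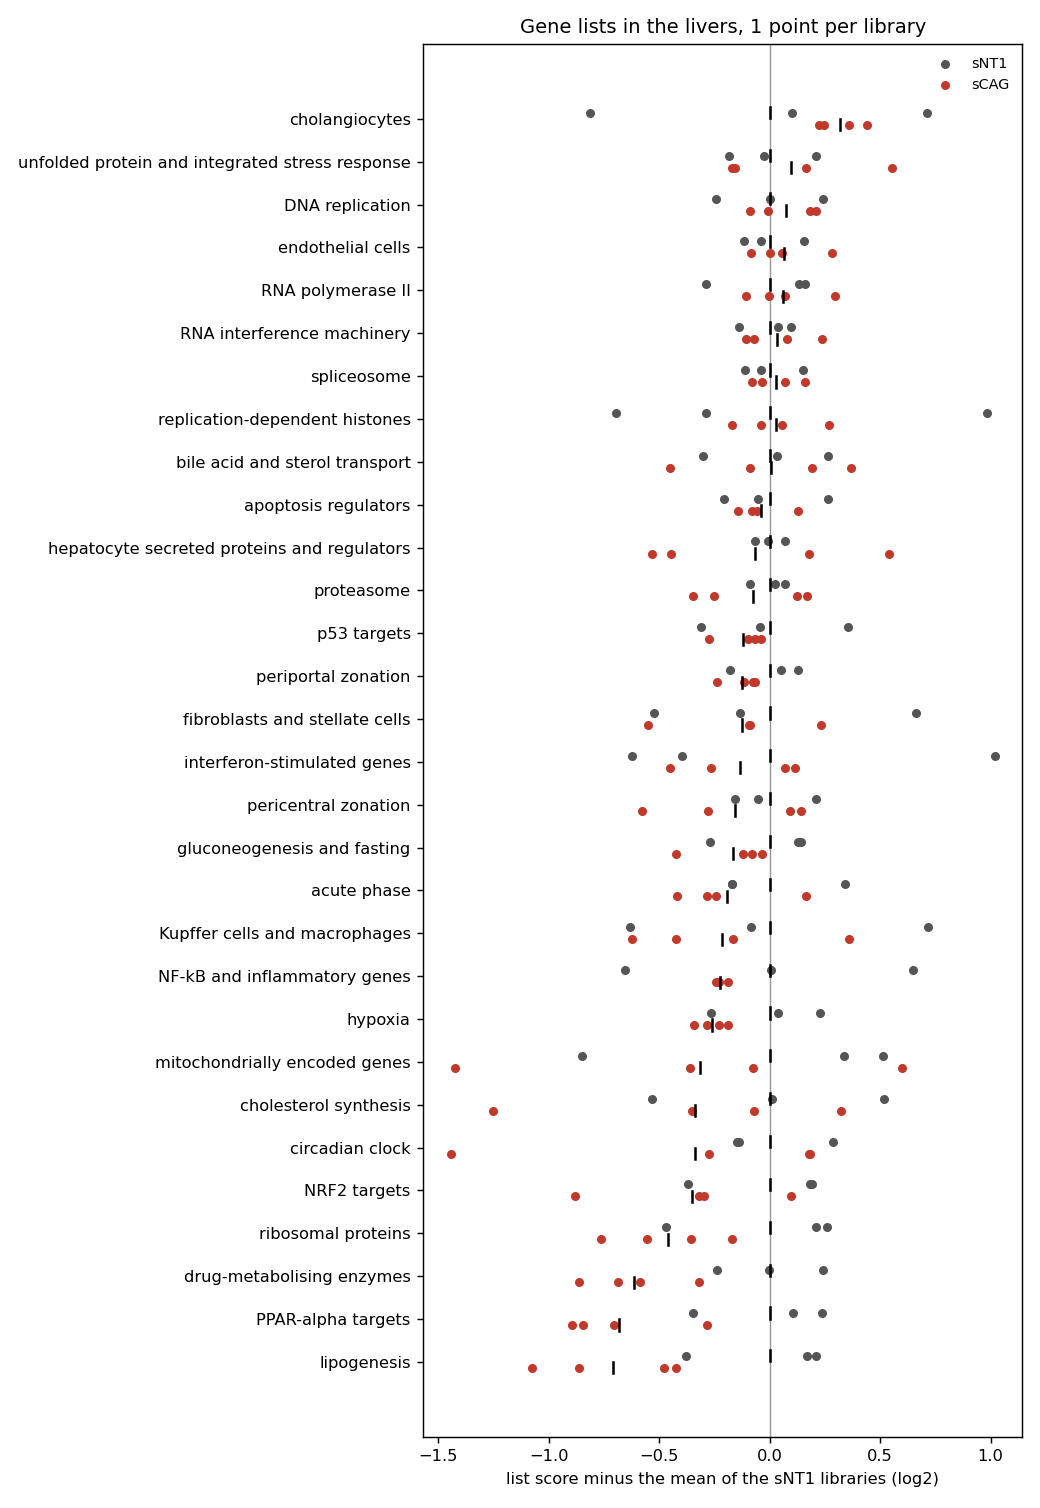
Score of each gene list in each liver library, as the difference in log2 from the mean of the sNT1 libraries, with the mean of each group as a line. All 4 sCAG livers lie below the 3 sNT1 livers for lipogenesis.

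The responses of tumour and liver were set side by side to ask whether the same genes moved in both. Across 7019 genes matched by symbol, the log2 fold changes had a Pearson correlation of -0.14 and a Spearman correlation of -0.14, each with p = 1e-04 over 10000 permutations, the smallest they can give. The genes are not independent replicates. Of 328 genes called in the tumour and tested in the liver, 107 had the same sign there, or 32.6%. Ribosomal protein genes are among those of opposite sign: 56 were called higher in the tumour, and 63 of 68 lay below 0 in the liver. The share was not computed without them or over all 7019 genes. The Pearson correlation was -0.03 without liver sNT1 replicate 4 (permutation p = 0.0221). Ribosomal protein scores differed by 1.02 in the tumour and -0.46 in the liver, and the difference between the tissues was 1.48 (exact permutation p = 0.00159, adjusted 0.0254 over 16 lists). With the 5 pairs of libraries that share arm and number relabelled together, the exact permutation p was 0.00615 and the adjusted p 0.0738, so the difference no longer passed. The next lists, the proteasome, the RNA interference machinery and NRF2 targets, had an adjusted p of 0.121 with independent relabelling.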

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

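The tests of mouse RNA in the tumours, of transcript length, and of the hepatocyte share were chosen only after the results were seen, as were the settings with thinned reads and with a size-factor covariate and the relabelling of same-numbered libraries together.

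A library lay far from the others of its group in 10 of 180 groups tested; chance alone gives this in about 1 in 20 groups, or 9 here. In sNT1 tumours, replicate 8 had the lowest RNA interference score (6.88, others 7.14 to 7.20) and the highest PSMD8 (97.4 normalized reads, others 61.7 to 69.1). Replicate 2 had the highest epithelial keratin score (6.83, others 6.60 to 6.66), and replicate 4 the lowest GUSBP2 (12.0, others 16.01 to 16.56). In sCAG tumours, replicate 3, the shallowest library, had the lowest scores for DNA replication (4.22), the spliceosome (6.29), epithelial-mesenchymal transition (6.37) and prostate lineage (3.49). Replicate 7 had the lowest DDIT3 (33.2, others 94.2 to 115). In sCAG livers, replicate 4 had the highest Ifit1 (70.4, others 19.9 to 21.6). Ribosomal protein genes moved differently in the tissues, by 1.48 on the log2 scale (exact permutation p = 0.00159, adjusted 0.0254 over 16 lists), but not past the threshold with libraries of the same arm and number relabelled together (exact permutation p = 0.00615, adjusted 0.0738).

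Ribosomal protein genes were higher in normalized reads in sCAG tumours, whose libraries held fewer reads. Processed pseudogenes had a median log2 fold change of 0.75, with 74 of 394 called higher and 6 lower, but were not tested as a class. Their share of all reads was 1.13% ± 0.0658 in sCAG and 1.17% ± 0.120 in sNT1 tumours (SD, n = 5 each). The sampling of fewer reads is argued against as the whole cause of the ribosomal protein rise. The median of these genes was 1.18 with every library thinned once to the shallowest. Its SE of 0.0570 is over 62 genes and does not measure the spread between tumours. What goes along with depth stays open, since the median was 0.43 with the size factor as a covariate. Mouse RNA counted on human genes stays open: pseudogenes exceeded their parent genes by a median of 0.0881 (95% interval -0.107 to 0.305, resampled over 61 pairs that share 41 parent genes). Transcript length or RNA integrity stays open too. Processed pseudogenes exceeded protein-coding genes of the same length by 0.227 (95% interval 0.121 to 0.327, resampled over pseudogenes), too near the bound of 0.2 to decide. Ribosomal protein genes could be among those protein-coding genes, and were not themselves compared with genes of the same length. The shares and the normalized reads of MALAT1 and NEAT1 were also lower in sCAG tumours. An effect of sCAG on the tumour cells remains a further candidate explanation.

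Lipogenesis genes had a lower median in sCAG livers and were called by camera at the preset correlation. They were not called with an estimated correlation (camera adjusted p = 0.211) or by fry (adjusted p = 0.506), and 0 of 17 genes passed. A single library does not account for the lower median, since the one nearest to 0 with 1 library left out was -0.51, without sNT1 replicate 4. The share of hepatocytes itself was not measured. A lower share as the whole cause of the fall is argued against by the hepatocyte genes, with a median of -0.0259. That lay above 0.5 of the lipogenesis median by 0.298 (95% interval 0.116 to 0.549, resampled over genes, not livers). However, camera called the hepatocyte list lower without sCAG replicate 3 (median -0.19, adjusted p = 0.00946). The hour of sampling or feeding may contribute and cannot be told apart, since too few livers were measured: over 7 livers with group means removed, lipogenesis and clock output scores had r = -0.61 and rho = -0.61 (exact permutation p = 0.111 and 0.188), and r = -0.75 without the 2 farthest livers. Camera called the clock list lower without sCAG replicate 1 (adjusted p = 0.0404), and clock output was -0.55 in sCAG relative to sNT1, which with a negative r goes with higher lipogenesis, opposite to the fall, so this test gives no evidence for it. An effect of sCAG on the liver also stays open.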

How the results depend on the processing

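Settings with edgeR under the authors' size factors or TMM, array weights, protein-coding genes, thinned reads, 3 libraries left out or a size-factor covariate were chosen only after seeing the data.

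The 577 tumour genes became 3193 at an adjusted p under 0.10 (1304 higher, 1889 lower), which follows from the looser threshold. For the rest the cause was not tested. The count was 1166 with edgeR and the authors' size factors, 1292 with TMM, 1201 with RLE, 1357 with upper quartile, 2097 with DESeq2, 4237 with limma-voom (1948 higher, 2289 lower) and 5108 with array weights (1942 higher, 3166 lower). Filters gave 1209 with a mean CPM of at least 1 (593 higher, 616 lower) and 2038 with a mean value of at least 1 (691 higher, 1347 lower). With no filter it was 633 (229 higher, 404 lower), of which 289 were shared. Pseudocounts gave 0 at 0.1 and 1750 at 5 (744 higher, 1006 lower). It was 0, with limma, under the covariate from the last letters of the codes (3448 at an unadjusted p under 0.05), for protein-coding genes alone (3678), without the 3 libraries of fewest reads (2598) and with the size factor, which differs between the arms, as a covariate (138). Without those 3 libraries 577 of 577 genes had the same sign, although the remaining libraries were part of both fits. Thinned reads gave 594 (301 higher, 293 lower), 279 of them shared, but with 3616 genes tested against 12139 in the main fit. Leaving out 1 library gave 0 to 4100 with limma and 0 to 4448 with edgeR, where it was 320 without sNT1 replicate 2, 1958 without sNT1 replicate 8 and 312 without sCAG replicate 10.

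The 5 tumour lists of 20 tested became 0 with an estimated correlation, 1 with fry and 8 without the 3 libraries of fewest reads. They became 5 to 6 with 1 library left out and 2 with thinned reads, where 13 lists were tested. NRF2 targets also lost their call with array weights (adjusted p = 0.0909), thinned reads (0.129), without the 3 libraries (0.172) and with the size-factor covariate (0.852). Histones lost theirs with thinned reads (0.0744), and the proteasome (0.852) and RNA polymerase II (0.315) with the covariate. The 6 liver lists became 0 with an estimated correlation, 0 with fry, 4 with array weights, where cholesterol synthesis (adjusted p = 0.742) and NRF2 targets (0.103) lost their calls, and 4 to 9 with 1 library left out. The liver gene count of 0 became 1 with DESeq2 and stayed 0 in the other settings run. The CTG difference of -0.02 was -0.12 for runs of 12 nt, -0.07 in coding sequence, -0.10 with thinned reads, 0.0158 for runs of 24 nt, 0.0785 in 3' UTRs, 0.00811 without the 3 libraries of fewest reads, and -0.11 to 0.0247 with 1 library left out. The tumour and liver correlation was -0.19 to -0.03 with 1 library left out and kept its sign in every setting run.

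Of 1059 comparisons for 39 tumour genes, 582 kept direction and side of the threshold, 453 lost the call, 9 gained it, 8 of them for MKI67 as a fall (lowest adjusted p 0.00191), and 15 reversed; of 633 for 29 liver genes, 612 kept both, 1 gained and 20 reversed. Over the settings run, log2 fold changes spanned 1.47 to 8.30 for ADCYAP1, 0.63 to 2.02 for RPS14, 0.33 to 1.93 for FTL and 0.39 to 3.73 for ZEB2, each lowest with the size-factor covariate. With the size-factor covariate MKI67 was 0.163 and CDKN1A -0.0191. DDIT3 was 0.0270 with RLE, 0.0769 with upper quartile, 0.0622 with limma-voom, 0.0107 with edgeR and the authors' size factors, 0.0607 with TMM, 0.317 with array weights and 0.212 without the 3 libraries. IFIT1 was 0.130 with limma-voom. Liver Cdkn1a was -0.806 with RLE, -0.788 with upper quartile, -0.749 with DESeq2, -0.388 and -0.0307 with pseudocounts of 0.1 and 5, -0.787 with edgeR and the authors' size factors and -0.811 with TMM. Liver Ddit3 was 0.114 with limma-voom and 0.147 with array weights. With 1 library left out, log2 fold changes spanned tumour DDIT3 -0.185 to 0.254, tumour IFIT1 -0.257 to 0.14, liver Mki67 -0.732 to 0.0918, liver Cdkn1a -0.798 to 1.42, liver Ifit1 -1.03 to 0.175 and liver Ddit3 -0.456 to 0.222.

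Liver libraries with the same number correlated at -0.215, 0.0865 and -0.131, so the numbers do not pair them. With the replicate block, 0 liver genes and 7 lists were called, the clock list added (adjusted p = 0.00918), Cdkn1a was -0.107 and Ddit3 0.222. No paired analysis was possible because the tumour arms share only 1 number. The liver alternatives for CTG repeats were not run.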

Other observations

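The comparisons with other splits of the samples were all planned before their results were seen.

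Chance is argued against, not excluded, for the count of tumour genes by this measure. Of 100 splits of the 10 tumours, drawn from 126 possible, the real one alone gave as many as 577, and the highest other gave 0. The real split also parts the tumours by depth and RN7SL2 share, which this measure cannot tell from treatment. At an unadjusted p under 0.05 the real split gave 4335 genes and the highest other 3741. That other split was close to the real one: it only exchanged sCAG replicate 1 with 1 sNT1 library. Drawn splits that mixed the arms further gave 33 to 1705 genes. Chance cannot be excluded for the 5 tumour lists, since 49 of 100 splits called as many and the highest other called 8. It cannot be excluded for the CTG-repeat genes either, with a p of 0.322 matched or passed in 16 of 100 splits and a lowest other p of 0.226. For the 6 liver lists, 24 of 35 splits called as many, with 13 as the highest other, so chance cannot be excluded. For liver genes the real count of 0 fixes the outcome at 35 of 35 splits, which says nothing about chance; the highest other split called 7.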
